A study of Mus musculus with 6 samples.

How the data were processed

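RNA from 6 MASE2 tumours was hybridised to Affymetrix whole-transcript mouse arrays, 1 array per tumour, with biotin-labelled sense target, per the labels' protocols. The groups, placebo and E2, and the replicate numbers were taken from the sample titles, 3 tumours per group, and the series' design text calls them biological replicates. The deposited values are log2 intensities, 1 per probe set and array, made by the authors with RMA, per the submitters' processing notes. The RMA software, its version and its annotation are not given in the sources used here. RMA corrects background, equalises the distributions of the arrays and summarises probes on a log2 scale, so it compresses large changes near background, and a tissue mixed into 1 sample can shift the other genes of that array. Each of the 34760 probe sets had a value on every array, and 0 columns of sample values were left unmapped.

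Probe sets were named through the platform annotation table. Of them, 21640 (62.3%) had 1 gene symbol, 1321 had several and 11799 were not listed there and are unnamed here. Of the single-gene probe sets, 21553 were matched by gene identifier to RefSeq names of assembly GRCm38.p6, which changed 0 symbols, and the table was used for names only. Where a gene had several single-gene probe sets (954 genes), the one with the highest mean over all arrays stood for the gene, leaving 19937 genes. Among the called genes, 1 had probe sets that differed in sign. No dim gene was removed. No detection call was used here, so a called gene below the lower quartile of genes on every array of its lower group was given a bound, with each such value raised to its array's lower quartile (for named genes below it on some arrays only, the number of arrays is given), a floor chosen after the data were seen. Genome coordinates are not used here, since the build behind the array values is not given in the sources used here.

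E2 and placebo were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on group means without covariates. Tests were two-sided, p was adjusted by the method of Benjamini and Hochberg over all genes, and an adjusted p under 0.05 was the threshold. Log2 changes are E2 minus placebo. With 3 arrays against 3, an exact permutation test of a gene cannot go below p = 0.10. The samples are separate tumours, so p-values measure the spread between tumours of each group.

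Before the data were examined, 30 gene lists were fixed from textbook knowledge of oestrogen response, ovarian biology, tumour processes and the cell types that a tumour sample could hold. They hold 530 symbols, of which 490 were measured, 5 under a newer name. Lists were tested with camera of limma at a preset correlation of 0.01, with p adjusted over the 30 lists. None of the 12 lists called this way passed with an estimated correlation. Fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, was run beside it. A further 12 lists (enterocyte, goblet cell, Paneth cell, enteroendocrine, mast cell, mesothelial, oocyte, follicle granulosa, luteal, adrenal, a second macrophage list and class II histocompatibility genes) were chosen after the data were seen.

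The named genes followed a rule fixed before the data were examined. It took Greb1, the 12 largest rises and 12 largest falls among called genes (without predicted genes, clones, pseudogenes, small RNAs and receptor segments), Esr1, Esr2, Pgr and Mki67, and from each list up to 6 called members by smallest p, or 3 members of smallest p where none was called. Genes named outside this rule, such as Reg3b, Zg16, Star, Fshr, Foxl2 and Amh, were chosen after their values were seen.

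The alternatives were leaving out each array in turn, the replicate number as a block, filters at the 25th percentile and the median of mean signal, the mean of a gene's probe sets, all probe sets tested singly, repeated quantile normalization, median centring, a trended and robust variance, array weights, adjusted p under 0.10, unadjusted p under 0.05 with a 1.5-fold change, camera with an estimated correlation, and fry. Leaving out placebo replicate 3 with a 2-fold minimum or with an estimated correlation was added after the data were seen. The limma and camera steps were tested on simulated data for the same 19937 genes, made with the spread of the real arrays and 200 changed genes. In them, 58.0% of log2 changes of 1 and 85.0% of log2 changes of 2 were recovered, with 12 false calls and 0 in the wrong direction, and 0 genes were called without any change. The list of changed genes was called and 0 of 30 unchanged lists were. The simulation was set up from the spread and the changed genes only, without lists whose genes vary together. Each gene varied independently with 1 spread on all arrays, and no simulated array stood apart as placebo replicate 3 did. The simulation therefore cannot judge the calls that camera made on the real lists at the preset correlation. Its rates of recovery and false calls may not hold for the real genes.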

Results

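Tumours grown from MASE2 cells were profiled on 6 single-colour whole-transcript arrays, 3 from SCID mice that carried placebo pellets and 3 from SCID mice that carried estradiol (E2) pellets. MASE2 cells are mouse ascites cells from a transgenic ovarian cancer model in which Cre recombinase switches on the SV40 T antigens in the ovarian surface epithelium. SCID mice lack mature T and B lymphocytes. Tumours were taken when the mice lost wellness, so the time of collection was set by the course of disease, and the labels give no day. The comparison asked which genes differed between E2 and placebo tumours, and the series title singles out Greb1. Values were log2 intensities summarised by RMA, and the array medians over 34760 probe sets lay between 4.84 and 4.97. The number of arrays limits the precision of each value.

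The array of placebo replicate 3 stood apart from the rest. Across the 19937 genes tested, which are not independent replicates, its Pearson r with the other arrays was 0.857 to 0.865, against 0.960 to 0.994 among those arrays. In that sample 448 genes were at least 2 log2 units above the mean of placebo replicates 1 and 2, and 51 were at least 2 log2 units below it. Its highest values against the other placebo tumours belonged to genes of the intestinal lining. Reg3b, an antimicrobial lectin, measured 12.15 there against 4.44 and 4.89 in placebo replicates 1 and 2. Zg16, a lectin secreted by goblet cells, measured 11.42 against 4.09 and 4.35. All 15 measured enterocyte markers, a list chosen after the values were seen, were higher in placebo replicate 3 than in every other array. The main comparison kept all 6 arrays, as fixed before the data were examined, and values without placebo replicate 3 stand beside most counts of called genes.

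**Figure D1:**
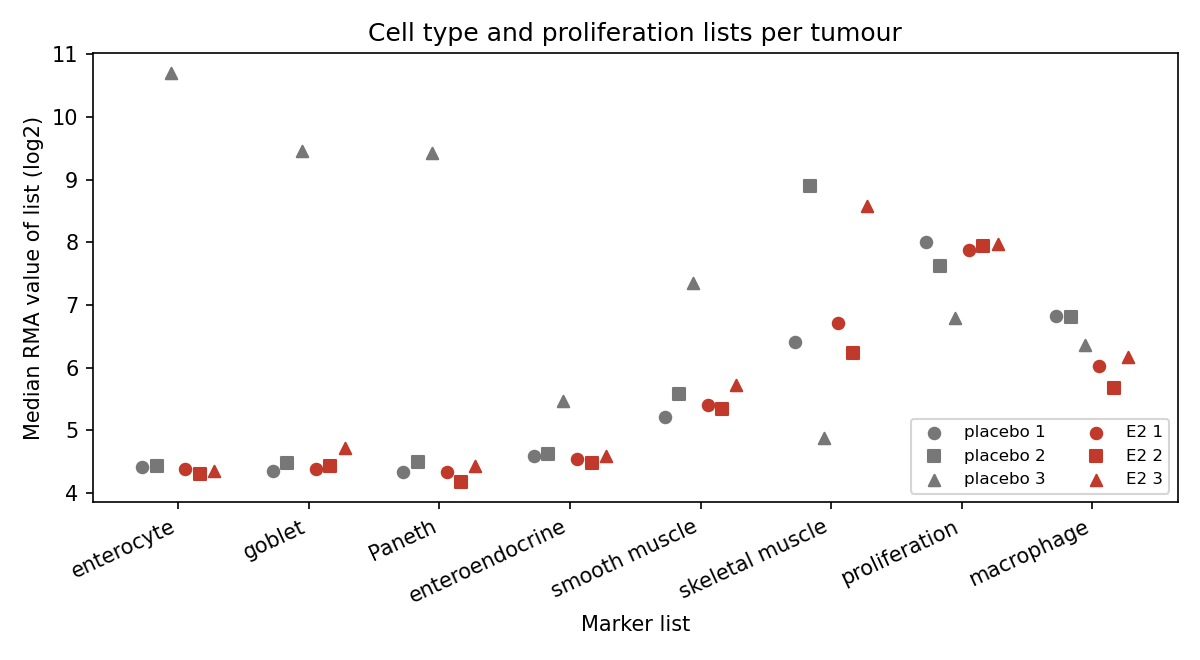
Median log2 RMA value of 8 marker lists (x axis) in each of the 6 tumours (y axis), with placebo tumours in grey, E2 tumours in red and replicates 1, 2 and 3 as circles, squares and triangles. The enterocyte, goblet, Paneth and enteroendocrine medians of placebo replicate 3 lie above those of every other tumour, and its skeletal muscle and proliferation medians lie below them.

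Greb1, an early oestrogen receptor target, was higher in all 3 E2 tumours than in all 3 placebo tumours. Its log2 value was 5.05 ± 0.30 (SD, n = 3) with placebo and 8.46 ± 0.06 (SD, n = 3) with E2. Greb1 rose by 3.41 on the log2 scale (SE 0.16, 95% confidence interval 3.03 to 3.80), a 10.7-fold difference with a limma adjusted p of 0.00131. The placebo tumours measured 4.88, 5.39 and 4.87, and the E2 tumours 8.44, 8.42 and 8.53. An exact two-sided permutation test of this gene gave p = 0.10, the smallest value that 3 against 3 allows. Pgr, the progesterone receptor gene and a known oestrogen target, rose by 2.64 on the log2 scale (SE 0.37, adjusted p = 0.0376). Esr1, the oestrogen receptor alpha gene, was 8.11 ± 1.53 (SD, n = 3) with placebo and 9.27 ± 0.10 (SD, n = 3) with E2, and the difference did not pass the test (adjusted p = 0.475). Placebo replicate 3 held the lowest Esr1 value, 6.35, and without it the difference went from 1.17 to 0.29 log2 (adjusted p = 0.125). Esr2, the oestrogen receptor beta gene, differed by -0.01 log2 (adjusted p = 0.953) and lay at 4.45 and 4.43 in the placebo and E2 tumours.

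**Figure D2:**
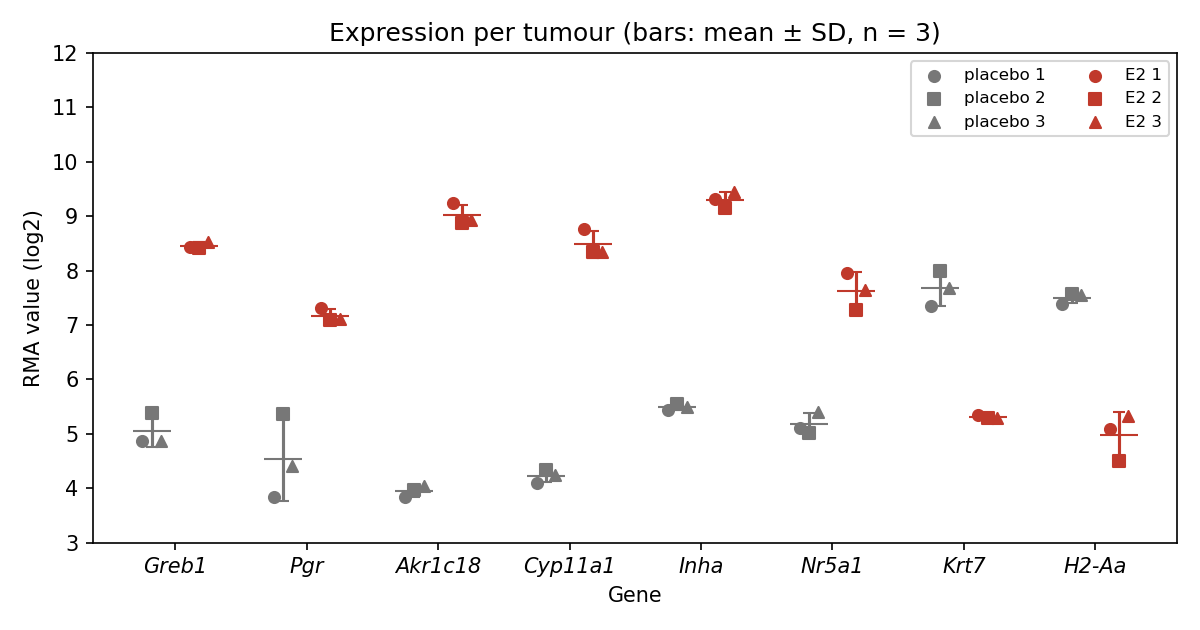
Log2 RMA value (y axis) of 8 genes (x axis) in each tumour, with placebo in grey, E2 in red, replicates 1, 2 and 3 as circles, squares and triangles, and bars for the mean ± SD (n = 3). All 8 genes passed the limma threshold, a choice that favours groups that do not overlap. The placebo and E2 values of each gene do not overlap, and Greb1 lies between 4.87 and 5.39 with placebo and between 8.42 and 8.53 with E2.

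In all, 211 genes were higher and 65 were lower in the E2 tumours at a limma adjusted p under 0.05, out of 19937 genes tested. Akr1c18, which encodes the progesterone-inactivating enzyme 20-alpha-hydroxysteroid dehydrogenase, measured 3.94 ± 0.10 with placebo and 9.02 ± 0.20 with E2 (SD, n = 3). Its placebo values lay below the lower quartile of genes on their arrays (4.22 to 4.39 over the 6 arrays) and were not shown to be above background. With each raised to its array's lower quartile, a floor chosen after the data were seen, Akr1c18 was at least 25.6-fold higher with E2 (limma adjusted p = 0.000223 on the measured values). In all, 11 of the higher genes lay below that quartile on every placebo array, and 3 of the lower genes on every E2 array. Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, rose by 4.26 on the log2 scale as measured (SE 0.14, adjusted p = 0.000442), and by 4.14 with the 2 of its 3 placebo values that lay below the quartile raised to it. Inha, the inhibin alpha subunit, rose 14.0-fold (log2 change 3.81, SE 0.10, adjusted p = 0.000223). Kctd14 (log2 change 3.86), Akr1cl (3.68), Pcp4l1 (3.47), Myl7 (3.38), Qrfprl (3.33), Prss35 (3.05), Lipg (3.01) and Emb (3.00) completed, with Greb1, the 12 largest measured rises among called genes under the naming rule. Qrfprl also lay below the quartile on 2 of the 3 placebo arrays (3.18 with these raised to it), and Akr1cl, Lipg, Pgr and Cyp26a1 on 1. The probes of Akr1c18 and Akr1cl, and of other close family members such as Hsd3b1 and Hsd3b6, may share sequence, so their separate values are uncertain. Without placebo replicate 3, 1276 genes were higher and 1039 lower, and these included all 276 genes called on 6 arrays, each in the same direction. The counts of higher and lower genes were 62 and 16 without placebo replicate 1, 170 and 34 without placebo replicate 2, 31 and 0 without E2 replicate 1, 37 and 6 without E2 replicate 2, and 37 and 7 without E2 replicate 3. Without E2 replicate 1, 2461 genes had an unadjusted limma p under 0.05.

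Of the 48 named genes that passed the test, 11 kept the call whichever array was left out. They were Greb1, Akr1c18, Inha, Cyp11a1, Qrfprl, Kctd14, Prss35, Myl7, Lipg, Cdh2 and Fgf7. The others lost it in at least 1 of these fits but kept their direction in all of them. For example, the log2 change ranged from -2.52 to -2.21 for Krt7, 1.90 to 2.22 for Kdr and 2.29 to 3.06 for Pgr. Leaving out E2 replicate 1, 2 or 3 ended 36, 32 and 33 of the 48 calls, and leaving out placebo replicate 1, 2 or 3 ended 27, 17 and 0.

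Of the 11 measured genes of the ovarian steroidogenic and granulosa list, 6 rose in the E2 tumours and 5 did not pass the test, or 8 rose with p adjusted over the list alone. Beside Cyp11a1 and Inha, the nuclear receptor gene Nr5a1, a regulator of steroidogenic genes, rose by 2.45 on the log2 scale and Inhba by 1.47. Hsd3b1 and Hsd3b6, below the lower quartile on every placebo array, rose by at least 1.02 and 0.86 against that floor (1.81 and 1.24 as measured). Star, the cholesterol carrier of steroidogenic cells, was 0.97 log2 units higher but missed the threshold (adjusted p = 0.0595). Fshr, the follicle-stimulating hormone receptor gene of granulosa cells, differed by -0.01, Foxl2 by -0.01 and Amh by -0.18. The median change of the list was 1.24 log2 (camera adjusted p = 4.11e-09; adjusted p = 0.393 with an estimated correlation), and 0.97 log2 with these 2 genes at the floor. Without placebo replicate 3 it was 1.33 log2 as measured and 8 of the 11 rose.

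Among the 37 measured genes of the oestrogen-responsive list, 5 rose (Greb1, Stc2, Cyp26a1, Pgr and Igf1) and 0 fell in limma over all genes, while 8 rose and 2 fell with p adjusted over the list alone. With placebo replicate 3 left out, 10 rose and 3 fell over all genes. Stc2, a secreted glycoprotein, rose by 1.90 on the log2 scale and Cyp26a1, which degrades retinoic acid, by 1.23. Igf1, the growth factor, rose by 1.48. The list as a whole did not pass (median change 0.05 log2, camera adjusted p = 0.138), and its median ranged from -0.074 to 0.070 without each array in turn. The steroid receptor and coregulator list held 15 genes, of which Pgr alone passed (median -0.20 log2, or -0.12 without placebo replicate 3, mean 0.02, camera adjusted p = 0.138), and 1 rose and 2 fell adjusted over the list alone. In the list of oestrogen and steroid metabolism, Akr1c18 alone passed among 12 genes, 3 rose adjusted over the list alone, and the list did not pass (median -0.23 log2, mean 0.26, camera adjusted p = 0.489). Mean and median differed in sign within each list, and the test placed the receptor list lower, as its median, and the metabolism list higher, as its mean. With placebo replicate 3 left out, limma gave 2 rises and 2 falls in the receptor list and 3 rises and 0 falls in the metabolism list, whose median was 0.14 log2.

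Cholesterol synthesis, hypoxia response and proliferation genes lay higher in the E2 tumours as lists. All 15 cholesterol synthesis genes had higher means with E2, yet 0 passed singly in limma or adjusted over the list alone (median 0.57 log2, camera adjusted p = 0.000137; adjusted p = 0.557 with an estimated correlation). In this list placebo replicate 3 lay 0.85 log2 units above the other placebo tumours, and without it 12 of the 15 rose and the median was 0.88 log2. Lss, lanosterol synthase, was 0.88 log2 units higher and Fdft1, squalene synthase, 0.98. In the angiogenic and hypoxia list 2 of 19 genes rose, 4 adjusted over the list alone. These were Adm, which encodes the vasodilator adrenomedullin (log2 change 2.51, adjusted p = 0.0268), and Angptl4 (0.80, adjusted p = 0.0468). The list median was 0.52 log2 (camera adjusted p = 0.000814; adjusted p = 0.557 with an estimated correlation). Placebo replicate 3 lay 0.74 log2 units above the other placebo tumours here, and leaving it out, 10 of the 19 rose, 1 fell and the median was 0.71 log2. Of 29 proliferation genes, 27 had higher means with E2, and Rrm2, a subunit of ribonucleotide reductase, rose by 0.96 on the log2 scale, as the 1 member that passed over all genes and over the list alone. The proliferation median was 0.45 log2 (camera adjusted p = 0.000260; adjusted p = 0.562 with an estimated correlation), and placebo replicate 3 lay 1.08 log2 units below the other placebo tumours in this list. Without that array 3 genes rose and 1 fell, the median was 0.12 log2 and the list no longer passed (camera adjusted p = 0.145). Mki67, the standard proliferation marker, differed by -0.34 log2 (adjusted p = 0.713), and by -0.82 without placebo replicate 3 (adjusted p = 0.0253).

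The unfolded protein response list (16 genes, median 0.24 log2, camera adjusted p = 0.00401) and the oxidative phosphorylation list (19 genes, median 0.20 log2, camera adjusted p = 0.0106) were higher with E2, with 0 members past the limma threshold over all genes or adjusted over the list alone. Each had an adjusted p of 0.557 with an estimated correlation. Without placebo replicate 3, 3 of the 16 and 12 of the 19 rose, and the oxidative phosphorylation median went from 0.20 to 0.43 log2. That array lay 0.50 log2 units above the other placebo tumours in the oxidative phosphorylation list. The first list lost its call without placebo replicate 1 and the second without placebo replicate 2. Ndufa4, of the respiratory chain, was 0.42 log2 units higher (adjusted p = 0.114), and Creld2, of the endoplasmic reticulum, 0.47 (adjusted p = 0.205).

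The largest falls among called genes included a claudin, a keratin and genes of antigen presentation. Cldn15, a tight junction claudin, fell by 2.55 on the log2 scale (SE 0.31, adjusted p = 0.0262), from 8.04 ± 0.60 to 5.49 ± 0.26 (SD, n = 3). Krt7, a keratin of simple epithelia, fell by 2.36 (SE 0.16, adjusted p = 0.00445). The class II histocompatibility genes H2-Aa, H2-Ea and H2-Ab1 fell by 2.53, 2.19 and 1.82, and Cd74, the invariant chain that accompanies their products, fell by 2.20. The probes of these H2 genes may share sequence, so their separate values are uncertain. Prr15 (-2.28), Rarres2 (-2.19), Crybg1 (-1.92), Ptprd (-1.79), Prelp (-1.76) and Pde3a (-1.75) were the other largest falls among called genes under the naming rule. In the epithelial and ovarian surface epithelium list of 23 genes, Krt7 fell and Gata4, a transcription factor of gonadal somatic cells, rose by 1.61 on the log2 scale, and 2 rose and 2 fell adjusted over the list alone. Its median was -0.74 log2 (camera adjusted p = 0.000992; adjusted p = 0.393 with an estimated correlation), and 11 of the 23 genes were highest in placebo replicate 3. Without that array 7 of the 23 fell, 2 rose and the median was -0.56 log2. A mesothelial list chosen after the data were seen, which shares 7 of its 15 measured genes with this list, had a median of -1.53 log2.

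Macrophage genes lay lower in the E2 tumours as a list (median -0.78 log2, camera adjusted p = 7.18e-06; adjusted p = 0.557 with an estimated correlation), while 2 of the 20 measured members passed singly and 2 lay above 0. Ctss, a lysosomal protease, fell by 1.04 on the log2 scale (adjusted p = 0.0324) and Ptprc, which encodes the leukocyte antigen CD45, by 1.11 (adjusted p = 0.0388). Adjusted over the list alone, 6 fell and 1 rose. Placebo replicate 3 lay 0.76 log2 units below the other placebo tumours in this list, and without it 15 of the 20 fell, 1 rose and the median was -1.01 log2.

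The endothelial list (18 genes, median -0.35 log2, camera adjusted p = 2.66e-05; adjusted p = 0.511 with an estimated correlation) was lower as a whole, but its 1 member past the limma threshold, the VEGF receptor gene Kdr, rose by 2.07 on the log2 scale (adjusted p = 0.0136). Adjusted over the list alone 9 fell and 1 rose. Over all genes, 4 endothelial genes fell and Kdr rose without placebo replicate 3. The adipocyte list (14 genes, median -0.58 log2, camera adjusted p = 0.000613; adjusted p = 0.511 with an estimated correlation) held 1 gene that fell, the fat cell hormone Adipoq (log2 change -0.85 as measured, and -0.59 with its E2 values, below the lower quartile on all 3 arrays, raised to it), and 7 that fell adjusted over the list alone. Among adipocyte genes, 7 fell and 1 rose without that array. T and B cell markers (14 genes, median -0.14 log2, camera adjusted p = 0.0103) and liver markers (12 genes, median -0.57 log2, camera adjusted p = 0.0203) were lower as lists, with 0 genes past the limma threshold singly or adjusted over the list alone and an adjusted p of 0.557 with an estimated correlation for each. The median level of the T and B cell list was 4.16 to 4.48 over the 6 arrays, near the lower quartile of genes (4.22 to 4.39). That of the liver list was 4.14 to 4.41 outside placebo replicate 3. Neither was shown to be above background. Among liver markers, 10 of 12 were highest in placebo replicate 3, which lay 1.36 log2 units above the other placebo tumours in this list. Without that array the liver median went from -0.57 to -0.12 log2 and the T and B cell median from -0.14 to -0.081, and neither list passed (camera adjusted p = 0.168 for T and B cell and 0.145 for liver markers), and T and B cell markers also lost the call without E2 replicate 3 and liver markers without E2 replicate 2.

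**Figure D3:**
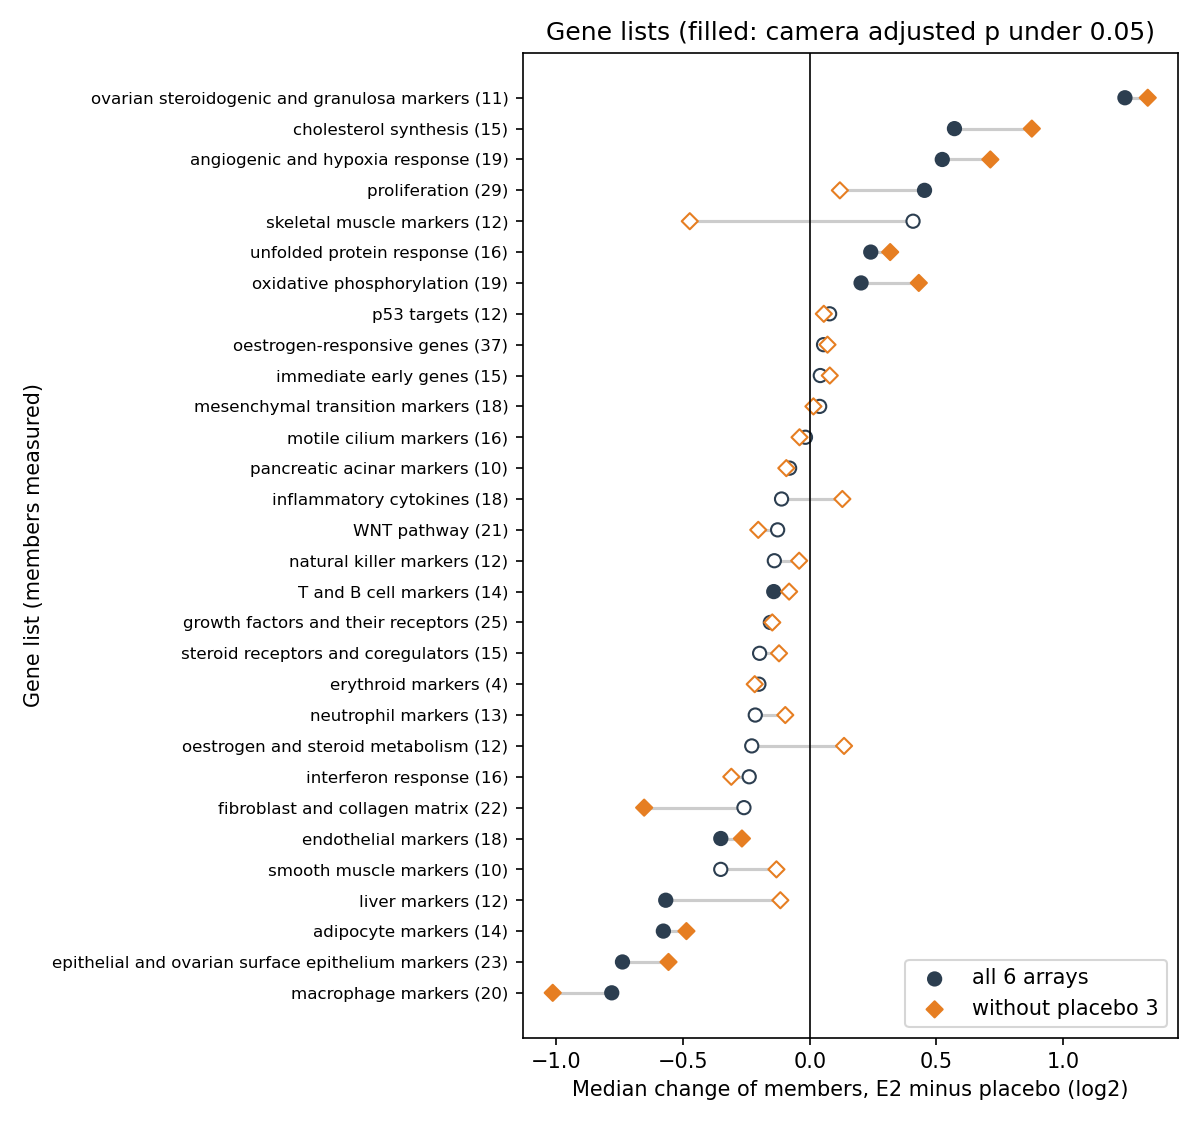
Median change of the measured members of 30 gene lists, E2 minus placebo in log2 units (x axis), for all 6 arrays (circles) and without placebo replicate 3 (diamonds), with the number of measured members in parentheses and filled symbols for a camera adjusted p under 0.05. The ovarian steroidogenic list has the highest median (1.24) and the macrophage list the lowest (-0.78).

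The remaining lists did not pass camera on all 6 arrays. Mesenchymal transition markers had 2 rises among 18 genes, Cdh2 (log2 change 2.18), which encodes N-cadherin, and Twist2 (1.53), also 2 adjusted over the list alone, with a list adjusted p of 0.222. Growth factors and receptors had 2 rises, Fgf7 (2.65) and Igf1, and 2 falls, the hepatocyte growth factor receptor gene Met (-1.18) and Pdgfa (-0.56), among 25 genes (adjusted p = 0.0929). Adjusted over the list alone, 3 of them rose and 4 fell. The WNT list had 1 rise, Dkk2 (1.49), among 21 genes (median -0.13 log2, mean 0.12, adjusted p = 0.220, placed lower), and the immediate early list had Egr1 (0.80) among 15 (median 0.04 log2, adjusted p = 0.675). Adjusted over the list alone, 4 WNT genes rose and 6 fell, and 4 immediate early genes rose and 1 fell. Neutrophil markers had 1 fall among 13 genes, Csf3r (-0.86), the receptor for granulocyte colony-stimulating factor, also over the list alone (list adjusted p = 0.0622). When placebo replicate 3 was left out, 3 mesenchymal genes rose and 3 fell, 5 growth factor genes rose and 3 fell, 3 WNT genes rose and 2 fell, 6 immediate early genes rose and 3 fell, and 1 neutrophil gene rose and 1 fell. The medians in that fit were 0.015 log2 for mesenchymal (0.039 on 6 arrays), -0.20 for WNT, 0.079 for immediate early and -0.096 for neutrophil genes (-0.21 on 6 arrays). Fibroblast and collagen genes had 0 calls over all genes in limma among 22, and 3 rose and 5 fell adjusted over the list alone (median -0.26 log2, camera adjusted p = 0.0821). Without placebo replicate 3, 11 fell and 1 rose, and the list passed (median -0.65 log2, camera adjusted p = 0.000213; adjusted p = 0.620 with an estimated correlation). Col3a1, a fibrillar collagen, differed by -1.40 log2 (adjusted p = 0.0704).

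No member of the other lists passed over all genes on the 6 arrays. Camera adjusted p was 0.0553 for smooth muscle (median -0.35 log2), 0.126 for natural killer (-0.14), 0.0929 for interferon response (-0.24) and 0.557 for inflammatory cytokine genes (-0.11). It was 0.731 for p53 targets (median 0.08 log2, mean -0.07, placed higher), 0.456 for motile cilium (-0.02), 0.190 for pancreatic acinar (-0.08), 0.557 for skeletal muscle (0.41) and 0.190 for erythroid markers (-0.20). Adjusted over the list alone, 1 natural killer gene rose, 2 interferon response genes rose and 3 fell, 2 inflammatory cytokine genes rose and 1 fell, and 0 genes of the other lists in this paragraph passed. Over all genes without placebo replicate 3, 1 interferon response gene rose and 4 fell, 3 inflammatory cytokine genes rose and 2 fell, and 3 p53 targets fell. In the same fit 1 smooth muscle gene rose and 1 fell, 1 natural killer gene rose and 1 erythroid gene fell, and the medians were -0.13 log2 for smooth muscle, -0.042 for natural killer, 0.13 for inflammatory cytokine, -0.040 for motile cilium and -0.47 for skeletal muscle genes. Skeletal muscle genes varied within groups, as Acta1, skeletal actin, was 8.90 ± 2.17 (SD, n = 3) with placebo and 10.03 ± 0.82 (SD, n = 3) with E2, and the difference went from 1.13 to -0.018 log2 without placebo replicate 3. The median level of the list was highest in placebo replicate 2 (8.90) and E2 replicate 3 (8.58), against 4.88 to 6.72 on the other arrays. Without placebo replicate 2 the median change of the list was 1.42 log2.

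Of the lists that did not pass on all 6 arrays, 8 passed camera when some array was left out. Smooth muscle markers passed, placed lower, without placebo replicate 1 (adjusted p = 0.00379), placebo replicate 2 (0.0360) or E2 replicate 3 (0.0316). Neutrophil markers passed, placed lower, without placebo replicate 1 (0.0273) or 2 (0.0184), and natural killer markers without placebo replicate 1 (0.0498). Median levels over the 6 arrays were 4.25 to 4.97 for neutrophil and 3.68 to 4.29 for natural killer markers, against a lower quartile of genes of 4.22 to 4.39. Mesenchymal transition markers (0.0262) and skeletal muscle markers (0.00651) passed, placed higher, without placebo replicate 2. Interferon response and growth factor genes passed, placed lower, without E2 replicate 3 (0.0209 each), as did fibroblast and collagen genes (0.0209), which also passed without placebo replicate 3. With an estimated correlation these calls had an adjusted p of 0.508 to 0.657.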

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

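The probe sets below were not part of any planned comparison. Among the 11799 probe sets without a gene name here, 27 were higher and 3 were lower in the E2 tumours at a limma adjusted p under 0.05 over all probe sets. They were singled out as a signal in data outside the comparison of named genes. The largest rise, probe set 10428619, was 3.17 log2 units (SE 0.20, adjusted p = 0.00440), and its values were higher in all 3 E2 tumours than in all 3 placebo tumours. What these probe sets measure, transcripts or array controls, was not analysed here.

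The count of genes past the threshold was set against other groupings of the arrays. The real grouping called 276 genes in limma, and the highest count among the other splits was 0, with 155 to 906 genes at an unadjusted p under 0.05 against 3298 in the real one. Of the 10 splits, 1 gave as many calls, the real one itself, and 10 splits are too few for a share under 0.05. Each other split put E2 and placebo tumours together, so differences between E2 and placebo widened the spread within its groups. Low counts were therefore likely in those splits, and the contrast cannot support the calls.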

How the results depend on the processing

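The Greb1 change kept its sign in all 15 alternatives that gave it and its call in all but the fit with the replicate number as a block (log2 change 3.41, adjusted p = 0.0514), with adjusted p between 2.74e-05 and 0.0514. Without each array in turn, it was 3.33 to 3.59, higher genes numbered 31 to 1276, lower genes 0 to 1039 and called lists 10 to 15. Whether the numbers pair the samples stays open. Deviations of same-numbered arrays had r = -0.029, -0.182 and -0.130 across genes, and no array was closest to its own number. With placebo replicate 3 so far from the other arrays, this check cannot exclude a shared cohort or day. The block left 10 higher and 0 lower genes in limma (2410 at an unadjusted p under 0.05) and 15 lists. Higher genes numbered 363 with median centring, and higher and lower genes 1026 and 760 with array weights (the weight of placebo replicate 3 was 0.149), 543 and 193 at adjusted p under 0.10, and 769 and 455 at an unadjusted p under 0.05 with a 1.5-fold change. The looser thresholds admit more genes by construction, and the cause of the other shifts was not tested. With placebo replicate 3 left out and a 2-fold minimum, an alternative chosen after seeing the data, 284 genes were higher and 256 lower. Camera with an estimated correlation called 0 lists (2 at an unadjusted p under 0.05), and 0 without placebo replicate 3 (3 at an unadjusted p under 0.05), also chosen after seeing the data. Fry called 2, ovarian steroidogenic (adjusted p = 0.00261) and epithelial genes (0.0361).

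Of the 30 lists, 7 of the 12 called kept the call without each array. The results that changed direction were called neither on all 6 arrays nor in the settings that turned them. The ranges that follow also span settings with a call, Mki67 at -0.82 without placebo replicate 3 (adjusted p = 0.0253) and skeletal muscle at 1.42 without placebo replicate 2 (camera adjusted p = 0.00651). Without each array, the log2 change ranged from -0.82 to 0.027 for Mki67, -0.018 to 2.13 for Acta1 and -0.059 to 0.021 for Esr2, and list medians from 0.018 to 0.15 for p53 targets, -0.032 to 0.096 for immediate early genes, -0.20 to 0.13 for inflammatory cytokines and -0.47 to 1.42 for skeletal muscle. The direction is that of the camera test for lists, so a median can keep its sign. Esr2 was 0.069 with quantile normalization, 0.070 with median centring and 0.015 with array weights. With dim genes left out at the 25th percentile, the medians were 0.013 for inflammatory cytokines and 0.079 for p53 targets, and at the median filter 0.41 for inflammatory cytokines, 0.29 for p53 targets, 0.018 for immediate early genes and 0.41 for skeletal muscle. Motile cilium markers were at 0.053 with quantile normalization, p53 targets at 0.16 and skeletal muscle at 0.49 with median centring, and inflammatory cytokines at 0.044 and skeletal muscle at -0.50 with array weights. Without placebo replicate 3 and with an estimated correlation, inflammatory cytokines were at 0.13 and skeletal muscle at -0.47. The cause of these shifts was not tested. Over the other named genes, 1134 values kept direction and call, 204 lost the call and 45 gained it, and over the lists 372, 49 and 32. Placebo values of Akr1c18, Hsd3b1 and Hsd3b6 lay below the lower quartile of their arrays (4.22 to 4.39), as did 2 of the 3 for Cyp11a1 and Qrfprl, where background limits how exactly a fold change is measured.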

Other observations

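The lists in this part were chosen after the data were seen, and so were the tests of a mislabelled tumour, of follicles, of a corpus luteum and of placebo replicate 3 as the source of the macrophage difference. Without placebo replicate 3, 14 of 15 mesothelial genes fell in the E2 tumours (list median -2.02 log2), against 2 on all 6 arrays (median -1.53), and 8 of the 15 are also in another list. Gpm6a, a membrane glycoprotein of mesothelium, was 10.22 and 10.36 in placebo replicates 1 and 2, 7.55 in placebo replicate 3, and 6.59, 5.04 and 6.29 in the E2 tumours. Mast cell genes had 8 of 10 falls without placebo replicate 3 and 0 on all 6 arrays in limma (median -0.60 log2). The mast cell protease gene Cpa3 was 6.42, 7.03 and 4.47 with placebo and 3.96, 4.03 and 4.27 with E2. Of 8 class II histocompatibility genes, 5 fell with and without that array. Among them was H2-Eb1 (log2 change -1.50, adjusted p = 0.00748), while H2-DMa differed by -0.02 and Ciita, the class II transactivator, by -0.34 (adjusted p = 0.133). Sfrp4, a secreted WNT antagonist, was 4.76, 7.13 and 4.13 with placebo and 10.05, 9.37 and 9.29 with E2 (adjusted p = 0.0694).

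Intestinal tissue in the sample is a candidate explanation for the distance of placebo replicate 3 from the other arrays. The enteroendocrine list, not looked at before, had a median 0.98 log2 units above placebo replicates 1 and 2, against a gap of 0.005 between those, and 13 of its 14 genes were highest in that array. Goblet, Paneth and enterocyte medians were 5.03, 5.42 and 6.57 log2 units higher, with 0, 1 and 1 of their genes above the array median in all the other tumours. A mislabelled E2 tumour was examined with Greb1, Akr1c18, Inha and Cyp11a1. Their median in placebo replicate 3 lay 0.0068 log2 units from the mean of placebo replicates 1 and 2, and none by more than 0.26. The last 3 were picked from a fit that counted this array as placebo, so their closeness cannot decide. Greb1, fixed beforehand, argues against it, at 4.87 there, 4.88 and 5.39 in placebo replicates 1 and 2, and 8.42 to 8.53 with E2. How far tissue mixed into the sample lowered these values was not tested. How intestinal RNA would have entered the sample stays open, and no biological explanation was tested.

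The rise of steroidogenic genes may come from the tumour cells or from host tissue. Host follicles could not be judged by the follicle granulosa list (median -0.011 log2, 7 genes). Its 4 genes that are in another list had been seen not to rise, which fixed the sign of that median. Of the rest, Amhr2 was 1.74 log2 units higher (limma adjusted p = 0.0704), Nr0b1 0.35 and Nppc 0.14, none past the threshold. The oocyte list had a median of -0.06. Adrenal tissue is argued against by the adrenal list (median -0.072 log2, highest member 0.30). A corpus luteum cannot be told apart from tumour cells, because Star, Hsd3b1, Scarb1 and Ptgfr had a median of 1.05 log2 but Ptgfr, abundant in luteal cells, was at -0.17, and 5 of the 9 luteal genes are in another list (list median 1.22). An effect of E2 on the tumour cells themselves stays open and untested.

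Fewer macrophages in the E2 tumours may account for the lower macrophage list. In a second list of macrophage and myeloid genes, not looked at before and sharing 0 genes with the others, 95.2% (20 of 21) were lower with E2. Without placebo replicate 3, 19 fell. The difference rested on placebo replicates 1 and 2, where the median level of this list was 6.14 and 6.19. Placebo replicate 3 lay at 5.41, within the range of the E2 tumours (5.33 to 5.46). Intestinal tissue in placebo replicate 3 is argued against, as the first list's median was -1.01 log2 without that array and -0.78 with it. Fewer cells and lower expression per cell were not separated.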
